A study of Mus musculus with 6 samples.

How the data were processed

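Gene expression was measured in neutrophils from the peripheral blood of wild-type mice and of mice without phd3, the prolyl hydroxylase gene now named Egln3. Per the labels, neutrophils were isolated from individual mice by negative magnetic selection, on a C57 background, and kept for 4 h in hypoxia at 3% oxygen before total RNA was extracted and labelled with biotin. There were 6 Affymetrix arrays, 3 per genotype, each taken as 1 mouse. No sample kept at normal oxygen was analysed here, so the comparison is between genotypes within hypoxia.

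The deposited values are MAS5 signal intensities on a linear scale, per the submitters' processing notes, and the version of MAS5 is not given in the sources used here. MAS5 combines the probes of a probe set within 1 array and scales each array to a common trimmed mean. In the deposited intensities, the mean after removing 2% of probe sets at each end was 99.97 or 99.98 on every array. Detection calls were not used here, so a low signal has no separate statement of presence or absence. The number of arrays limits the precision, and low MAS5 signals vary more on the log scale than high ones.

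Of 45101 probe sets, 64 were controls and were left out. Among the others, 34945 had 1 gene symbol in the annotation table used, 932 had several and 9160 were unnamed here. The named probe sets stood for 18193 genes, of which 18033 matched the RefSeq gene table of mouse assembly GRCm38.p6 by gene ID, and 0 symbols changed through that match. That table served for names and, through its start positions, for ranking genes by distance from Egln3. Its coordinates were put to no other use, since the files name no genome build. Each gene was represented by its probe set with the highest mean log2 value. Genes with a mean log2(signal + 16) below the median of the non-control probe sets, 5.90, were not tested. This left 10960 genes, of which 6917 had several probe sets.

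Genotypes were compared on log2(signal + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the prior variance, two-sided), with no block. Benjamini-Hochberg adjustment ran over all genes tested, and genes with an adjusted p under 0.05 were called. Fold changes are on the log2(signal + 16) scale, which understates changes of dim genes, and are given as phd3 null minus wild type with the standard error (SE) of the fit. There were 26 gene lists fixed before the data were examined, and 25 of them had at least 3 tested members. These were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists. Calls were repeated with a correlation estimated for each list and with fry. With an estimated correlation, camera also takes the residual degrees of freedom of the fit, 4 here and 2 with the replicate block described below. Its p-values then rise even where the estimated correlation is near 0, so a call lost in this way need not come from correlation.

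Sample numbers in the labels run from 1 to 3 in both genotypes, and the source labels give same-numbered samples of the genotypes a shared code. The deviations of same-numbered arrays from their group means correlated across genes at 0.292, 0.151 and 0.474 for pairs 1 to 3. Pairs with different numbers gave correlations from -0.363 to 0.177, and 5 of the 6 arrays correlated best with the array of their own number. The exception was phd3 null sample 2, at 0.177 with wild-type sample 1 and 0.151 with its own number, so the correlations do not show how samples 1 and 2 pair. Every same-numbered pair was above 0.1 and shared a source code, so the numbers were taken to pair the samples. The fit with the replicate number as a block, planned as an alternative, is given beside results whose call it changes.

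Genes named in the text followed a rule written before the data were examined. It takes Egln3, Siva1, Bcl2l1 and Nfkbia, genes past the threshold, otherwise the 10 genes of smallest p in each direction, said not to pass, members of lists past the threshold, and up to 4 members of smallest p from each list that camera called. Genes with an adjusted p under 0.10 in the paired fit, and other list members named for their values, were chosen after the values were seen.

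The code was tested on simulated data with the real levels and pair effects of the 10960 genes and the spread of the paired fit. In them 50 genes were changed at each size in the phd3 null against wild-type comparison. Without the block, 4 of 50 genes lowered by 3 log2 units were recovered, 0 of 50 at 2 units lower, 0 of 50 at 1 unit lower and 0 of 50 at 1 unit higher, with 0 false calls. With the block, 46, 19, 5 and 14 of 50 were recovered, with 5 false calls. A shifted list was found by both fits, and 1 of 24 unshifted lists was called in each. Pair effects were built in, so the higher recovery with the block does not show that the block suits the real data. The noise was independent between genes, so the list check does not cover correlated lists. In the real data without the block, the estimated correlation was 0.60 for markers of natural killer cells and 0.62 for glycolysis genes. With the block it was 0.059 and 0.37.

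Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter or a filter at the 70th percentile, every probe set on its own, the mean of a gene's probe sets, no trend, array quality weights, the block, and leaving out each array in turn. Combinations of the block with these settings and removal of whole pairs were added after seeing the data.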

Results

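The data are expression profiles of blood neutrophils from 3 wild-type and 3 phd3 null mice after 4 h at 3% oxygen. PHD3, encoded by Egln3, is an oxygen-dependent prolyl hydroxylase of the family that marks hypoxia-inducible factor (HIF) for degradation, and Egln3 itself is induced by hypoxia in many cells. The design asks how the transcriptome of hypoxic neutrophils differs without it. The median signal per array was 52.1, 51.7 and 64.2 in phd3 null samples 1 to 3 and 49.4, 51.1 and 60.3 in wild-type samples 1 to 3. Both arrays of replicate 3 stood apart from the rest, with median correlations to the other arrays of 0.739 (phd3 null) and 0.788 (wild type), against 0.838 to 0.866 for the other 4. These 2 arrays also had less Gapdh 3' signal, 3107.5 and 3491.4 against 6656.3 to 8276.6. Several hypoxia-induced genes were low in both. Bnip3 was at 202.3 and 195.7 against 2575.4 to 4817.4, and Ldha at 1166.5 and 895.9 against 4149.7 to 4997.2. Pdk1 was at 237.1 and 190.1 against 935.3 to 1960.4. Not every such gene was low, with Cited2 at 666.1 and 614.6 against 497 to 635.4. The cause was not tested. The heat shock gene Hspa1a was at 1157.9 and 1175.1 in them against 67.2 to 171.3 elsewhere. Signal of Cd79a, a B cell receptor component, was 424.9 and 331.3 in these arrays against 25.2 to 102.4.

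The targeted gene was low in every phd3 null sample. Egln3 signal by the brighter of its 2 probe sets was 87.2, 29.6 and 73.5 in phd3 null samples 1 to 3 and 2088, 1733.9 and 327 in wild-type samples 1 to 3. The means were 63.4 ± 30.1 (SD, n = 3) and 1383 ± 931 (SD, n = 3), a log2 fold change of -3.85 (SE 0.65) on the log2(signal + 16) scale. The phd3 null signals lay around the array medians and no detection calls were used, so the size of the fold depends on the pseudocount, with -4.18 for 1 and -3.20 for 64. Within pairs the log2 differences were -4.35, -5.26 and -1.94. The smallest, in pair 3, went with the lower wild-type signal of 327, on an array where several hypoxia-induced genes were also low. The other probe set gave means of 39.1 ± 35.2 and 277.3 ± 147 (SD, n = 3) and a log2 fold change of -2.52. The part of the gene that was deleted is not given in the labels, so the low signal does not tell whether the probe sets lie inside it. Without the block, Egln3 did not pass in limma over all genes (adjusted p = 0.9996), although its unadjusted p was the smallest of all genes tested and it passed adjusted over the list alone among the oxygen-sensing genes (adjusted p = 0.00219). With the replicate block the SE was 0.43 and Egln3 passed (adjusted p = 0.00140). Leaving out wild-type sample 3 also gave a call (log2 fold change -4.68, adjusted p = 0.0170).

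**Figure D1:**
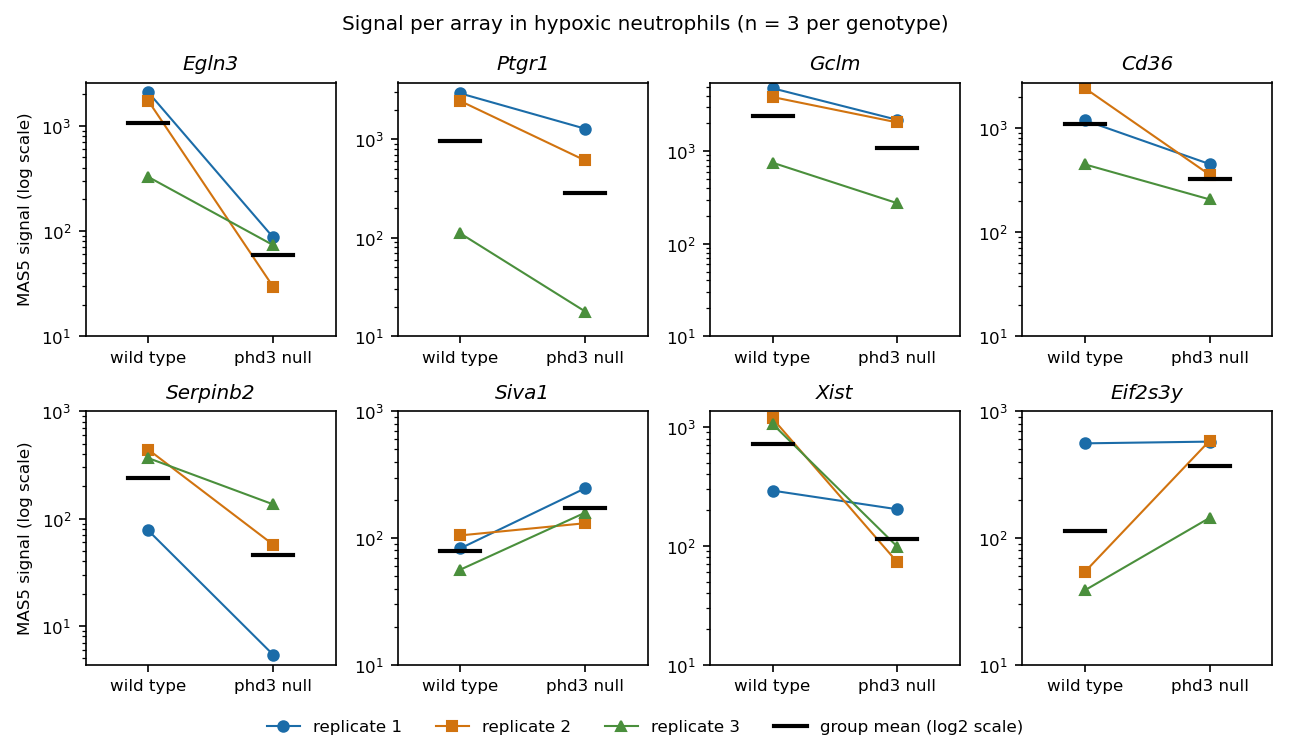
MAS5 signal (log scale, with a separate range for each gene) in wild-type and phd3 null neutrophils, each point 1 array, lines joining same-numbered samples and black bars the group means taken as log2(signal + 16). Egln3 is lower in phd3 null in 3 of 3 pairs (327 to 2088 against 29.6 to 87.2), as are Ptgr1, Gclm, Cd36, Serpinb2 and Xist, while Siva1 is higher in 3 of 3.

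Beyond Egln3, 1 gene passed in the paired fit. Ptgr1, which encodes an NADPH-dependent reductase that inactivates leukotriene B4 and prostaglandins, was lower in 3 of 3 pairs, with a log2 fold change of -1.69 (SE 0.24, adjusted p = 0.0128). Its signal was 635.8 ± 632 in phd3 null and 1828 ± 1506 in wild-type samples (SD, n = 3), the SD being large because both samples of replicate 3 were low, at 17.8 and 110.6. Without the block its log2 fold change ran from -3.16 without wild-type sample 3 to -0.11 without phd3 null sample 3. Next in order, not passing in the paired fit, were the scavenger receptor gene Cd36 (log2 fold change -1.71, SE 0.28, adjusted p = 0.0536), Xist (-2.49, adjusted p = 0.0824), Serpinb2, encoding plasminogen activator inhibitor 2 (-2.03, SE 0.37, adjusted p = 0.0901), and Gclm, the modifier subunit of glutamate-cysteine ligase in glutathione synthesis (-1.15, SE 0.21, adjusted p = 0.0901). Each was lower in phd3 null in 3 of 3 pairs. When an array was left out without the block, the log2 fold change ran from -2.34 to -1.14 for Cd36, -3.12 to -2.14 for Xist, -2.75 to -1.27 for Serpinb2 and -1.98 to -0.19 for Gclm. The paired counts were 2 genes at an adjusted p under 0.05, both lower, and 616 genes at an unadjusted p under 0.05 (279 higher, 337 lower), against 548 expected by chance. Without the block, limma called 0 of 10960 genes at an adjusted p under 0.05 and 191 had an unadjusted p under 0.05 (114 higher, 77 lower). Genes whose groups did not overlap numbered 758, or 6.92%, where chance gives 10%. The 2 paired calls were lost when the trend in the prior variance was left out or a gene's probe sets were averaged (0 genes in each). Ptgr1 was also lost with quantile normalization and passed in 11 of 14 block settings (adjusted p from 6.78e-05 to 0.896).

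The genes of smallest p without the block, none of which passed (adjusted p = 0.9996 for each), were mostly dim. Those higher in phd3 null were Fut4-ps1, Mrs2, Ccne1, Cadm3, Mon1b, Ctrc, Prkar1b, Zfp414, Padi4 and Hdac11, with log2 fold changes from 1.28 for Padi4 to 2.00 for Ctrc. Padi4, the histone-citrullinating enzyme of neutrophils, had a signal of 235.9 ± 77.4 in phd3 null and 87.3 ± 33.1 in wild type (SD, n = 3). Ccne1, which encodes cyclin E1, was at 124.9 ± 41.3 against 30.6 ± 7.80, and Mrs2, a mitochondrial magnesium channel gene, at 114.2 ± 16.7 against 24.3 ± 14.8 (SD, n = 3). Fut4-ps1 is a pseudogene of the fucosyltransferase gene Fut4, and whether its probe set also reads Fut4 was not examined. Those lower were Egln3, Xist, Slc35e3, Tmem63a, Plk5, Phf7, Cdc42ep5, Fbxo34, Fasn and Golga7b, with log2 fold changes other than those of Egln3 and Xist from -1.90 for Phf7 to -1.34 for Slc35e3. Fasn, the fatty acid synthase gene, had a signal of 35.7 ± 38.8 in phd3 null and 148.7 ± 38.6 in wild type (SD, n = 3). The smallest unadjusted p of these after Egln3 was 0.00132, for Xist.

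Sex-linked transcripts varied between the arrays. Xist, the RNA of the inactive X chromosome, had a signal of 203.4, 72.9 and 98.5 in phd3 null samples 1 to 3 and 292, 1180.4 and 1061 in wild-type samples 1 to 3. The Y-linked gene Eif2s3y was at 576.2, 585.4 and 144.3 in phd3 null and at 558.4, 54 and 38.7 in wild type. Of the 3 tested sex-linked genes, 1 passed adjusted over the list alone without the block (Xist, adjusted p = 0.00395) and 2 with it, and 0 passed over all genes in either fit. The list of sex-linked genes was not called by camera (adjusted p = 0.754). Camera looks for a shared direction, and the list joins Xist with Y-linked genes, which move in opposite directions with sex. The missing call therefore does not bear on a difference in sex.

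Natural killer (NK) cell markers were the list with the lowest median. Of 13 tested members 12 were lower in phd3 null, 7 of them in every pair, with a median log2 fold change of -0.60 (pairs -0.28, -0.81 and -0.60). Members of smallest p were Klrk1, the NKG2D receptor gene (-1.21, SE 0.63), Klre1 (-1.25, SE 0.78), the granzyme gene Gzma (-1.13, SE 0.76) and Klra8 (-1.02, SE 0.75). When 1 array was left out, they ran from -1.83 to -0.64 for Klrk1, -2.05 to -0.33 for Klre1, -1.70 to -0.26 for Gzma and -1.60 to -0.13 for Klra8. Over all genes 0 members passed, and adjusted over the list alone 0 passed without the block and 4 with it. Camera called the list (adjusted p = 0.0177, and 1.35e-05 with the block), but with an estimated correlation p = 0.280 and adjusted p = 0.994, and with the block p = 0.0555 and adjusted p = 0.747. The call was lost without phd3 null sample 1 (median -0.13, adjusted p = 0.498), wild-type sample 2 (-0.35, adjusted p = 0.526) or wild-type sample 3 (-0.53, adjusted p = 0.105).

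Immediate early and heat shock genes were the other called list. Of 25 tested members 22 were lower in phd3 null, 9 in every pair, with a median of -0.20 (pairs -0.33, -0.28 and -0.17). The MAP kinase phosphatase gene Dusp1 had a signal of 2279 ± 628 in phd3 null against 4257 ± 1124 in wild type (SD, n = 3; log2 fold change -0.90, SE 0.37). Egr2 differed by -1.16 (SE 0.75), the small heat shock protein gene Hspb1 by -0.63 (SE 0.33) and Atf3 by -0.38 (SE 0.30). Fos and Junb were not lower, at 0.11 (SE 0.30) and 0.11 (SE 0.38), and Hspa1a followed the replicate more than the genotype, as given above. Over all genes 0 members passed, and adjusted over the list alone 0 passed without the block and 2 with it, Dusp1 and Egr2. Camera gave adjusted p = 0.0430 (0.00495 with the block). With an estimated correlation it gave p = 0.234 and adjusted p = 0.994, and with the block p = 0.0597 and adjusted p = 0.747. With the block the estimated correlation was 0.000856, under the preset 0.01, so this rise in p came from the fewer degrees of freedom. The call was lost with quantile normalization (adjusted p = 0.279), with a pseudocount of 1 (0.0702), and without phd3 null sample 1 (median -0.15, 0.148), phd3 null sample 2 (-0.04, 0.485), wild-type sample 1 (-0.29, 0.0572) or wild-type sample 3 (-0.10, 0.410).

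**Figure D2:**
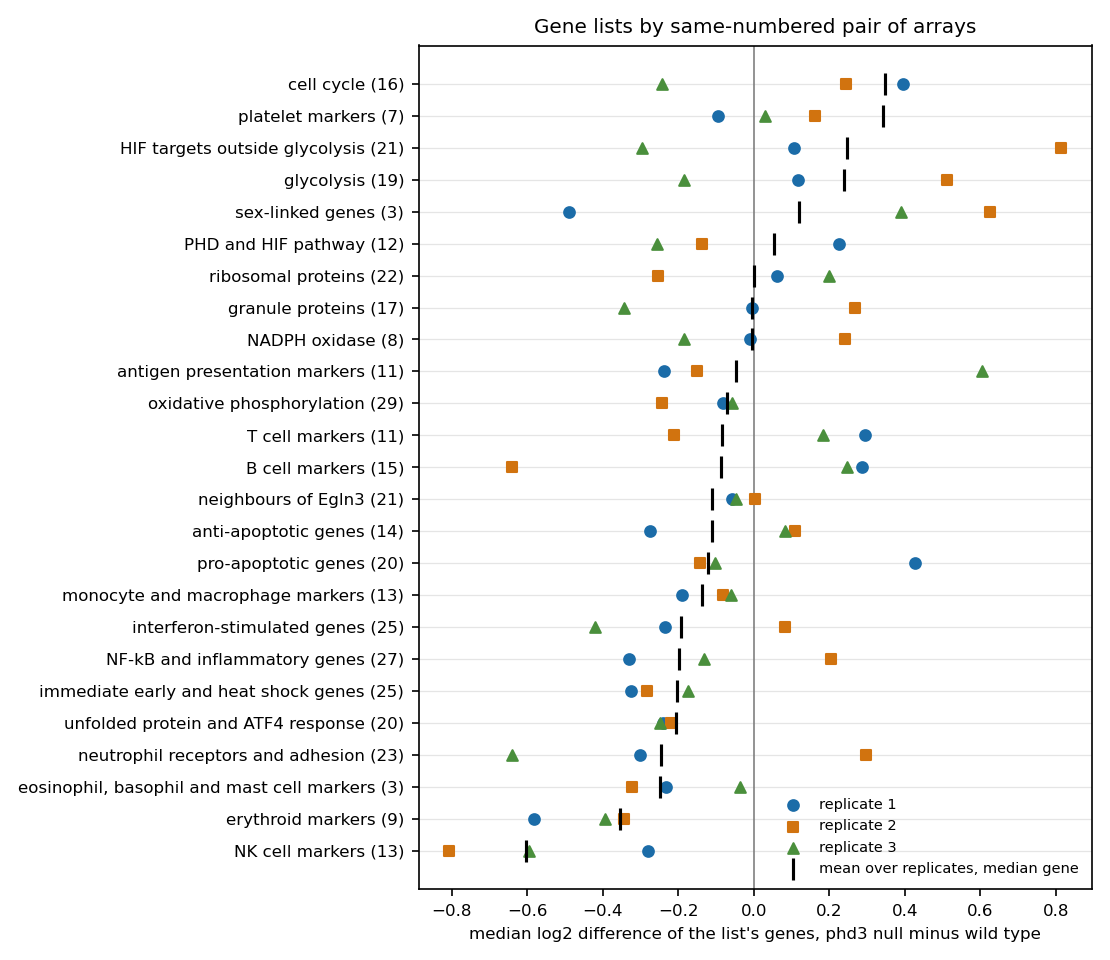
Median log2 difference (phd3 null minus wild type) of the tested genes of each of 25 lists, by same-numbered pair of arrays (coloured points) and for the mean over pairs (black ticks), with the number of genes tested in brackets. NK cell markers have medians of -0.28, -0.81 and -0.60 in pairs 1 to 3, whereas glycolysis genes have 0.12, 0.51 and -0.18.

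Hypoxia-response genes did not pass as lists. Of 19 glycolysis genes 16 were higher in phd3 null, with a median of 0.24 (pairs 0.12, 0.51 and -0.18). Pfkp, encoding the platelet phosphofructokinase, differed by 0.33 (SE 0.40), and Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, by 0.46 (SE 0.92). HIF targets outside glycolysis had 13 of 21 members higher, with a median of 0.25 (pairs 0.11, 0.82 and -0.30). Ndrg1 differed by 1.06 (SE 0.53) and the heme oxygenase gene Hmox1 by -0.99 (SE 0.66), the 2 members that passed adjusted over the list alone with the block, and 0 passed without it. In glycolysis 0 passed in either fit. Camera gave adjusted p = 0.452 for glycolysis and adjusted p = 0.427 for the other HIF targets. Both lists were called higher without pair 3, the arrays that stood apart (medians 0.47 and 0.46, adjusted p = 0.00894 for each, and 0.896 with an estimated correlation), without phd3 null sample 3 (medians 0.72 and 0.82, adjusted p = 1.21e-05 and 6.44e-05), without wild-type sample 1 (0.48 and 0.48, 0.0409 for each), and with array quality weights (0.0190 and 0.0152). With the block added, glycolysis was called in 4 of 16 settings and the other HIF targets in 2 of 16. For glycolysis these were a pseudocount of 64, quantile normalization, every probe set and the removal of pair 3. The block with an estimated correlation gave adjusted p = 0.981 for each. Without a call, the medians were -0.10 and 0.01 without phd3 null sample 1, -0.11 and -0.17 without phd3 null sample 2, and -0.36 and -0.13 without wild-type sample 3. Among the oxygen-sensing enzymes and HIF subunits, 7 of 12 were higher, and Egln3 was the member past the threshold with the block. Egln1 and Egln2, its paralogs, differed by 0.40 (SE 0.77) and 0.28 (SE 0.39). The list's median was 0.05 while its mean was -0.30, and camera gave adjusted p = 0.662.

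Survival genes showed no shift as groups. Siva1, a pro-apoptotic gene, and Bcl2l1, which encodes the survival protein BCL-XL, are genes that the published study is known to discuss, so their values are not independent evidence of a direction. Siva1 had a signal of 179.0 ± 60.7 in phd3 null and 81.5 ± 24.3 in wild type (SD, n = 3), a log2 fold change of 0.99 (SE 0.37), higher in 3 of 3 pairs. It passed among these 2 genes adjusted over the list alone (adjusted p = 0.0471) and not over all genes (adjusted p = 0.9996, unadjusted p = 0.0235). The 4 probe sets of Siva1 disagreed, the others giving 0.96, -0.21 and -0.37. Bcl2l1 differed by -0.02 (SE 0.30), with 355.9 ± 65.8 against 356.1 ± 8.37 (SD, n = 3). Of 20 pro-apoptotic genes 9 were higher and 11 lower, with a median of -0.12 and a mean of -0.01 (camera adjusted p = 0.977). Casp6, encoding an executioner caspase, differed by 1.40 (SE 0.49), and Fadd, a death receptor adaptor gene, by -0.84 (SE 0.45). Of 14 anti-apoptotic genes 4 were higher and 10 lower, with a median of -0.11 (camera adjusted p = 0.819). In both lists 0 members passed, over all genes or adjusted over the list alone.

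Neutrophil receptor and adhesion genes were lower in 19 of 23 cases, with a median of -0.25 (pairs -0.30, 0.30 and -0.64). Tlr4, the lipopolysaccharide receptor, differed by -0.64 (SE 0.37), its co-receptor Cd14 by -0.79 (SE 0.51) and the complement receptor C5ar1 by -0.58 (SE 0.57), while Csf3r, the G-CSF receptor, differed by 0.39 (SE 0.50). Camera gave adjusted p = 0.190 without the block and called the list with it (adjusted p = 0.0459, and with an estimated correlation p = 0.444 and adjusted p = 0.981). It passed in 8 of 16 block settings, and not with a pseudocount of 1, quantile normalization, no filter or array quality weights. With no block, the list was called when phd3 null sample 1 (median -0.44, adjusted p = 0.00926), phd3 null sample 2 (-0.51, 0.00745) or wild-type sample 3 (-0.54, 0.00467) was left out. The median was 0.18 without phd3 null sample 3 (adjusted p = 0.247) and 0.00 without wild-type sample 1. NF-kB and inflammatory genes were lower in 19 of 27 cases, with a median of -0.20 (pairs -0.33, 0.21 and -0.13) and adjusted p = 0.216. Among them the chemokine genes Ccl3 and Cxcl2 differed by -0.74 (SE 0.52) and -0.66 (SE 0.64), and Nfkbia, an NF-kB inhibitor gene near Egln3, by -0.23 (SE 0.37). This list was called lower without phd3 null sample 1 (-0.36, adjusted p = 0.0137) or wild-type sample 3 (-0.46, 8.47e-04), and its median was 0.11 without phd3 null sample 3 and 0.14 without wild-type sample 1, not called. With all arrays and an estimated correlation, adjusted p was 0.994 for both lists without the block. In these lists 0 members passed, over all genes or adjusted over the list alone, in either fit.

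Granule protein genes were higher in 8 and lower in 9 of 17 cases, with a median of 0.00 that turned to 0.15 with quantile normalization. Cd177 differed by 0.76 (SE 0.31) and S100a9 by -0.46 (SE 0.40). NADPH oxidase genes were higher in 3 of 8 cases (median 0.00, and from -0.44 to 0.47 when 1 array was left out). Genes of the unfolded protein and ATF4 response were lower in 17 of 20 cases, with medians of -0.24, -0.22 and -0.25 in the 3 pairs (camera adjusted p = 0.215). Leaving out 1 array moved the median of this list between -0.31 and -0.08. Hspa5, the chaperone BiP, differed by -0.43 (SE 0.50). Interferon-stimulated genes were lower in 16 of 25 cases (median -0.19), with Oas2 higher by 1.28 (SE 0.43). Oxidative phosphorylation genes were lower in 18 of 29 cases (median -0.07), ribosomal protein genes in 11 of 22 (median 0.00), and cell cycle genes were higher in 11 of 16 (median 0.35, adjusted p = 0.232). None of these 7 lists was called by camera in either fit, and 0 of their members passed over all genes or adjusted over the list alone. Without wild-type sample 3 the cell cycle list was called higher (0.52, adjusted p = 0.0375), and without phd3 null sample 3 the ribosomal list was called lower (-0.37, adjusted p = 0.00965). The cell cycle median was -0.11 without wild-type sample 1 (adjusted p = 0.848), and the ribosomal one 0.30 without wild-type sample 3 (0.105). With all arrays and an estimated correlation, adjusted p was 0.994 for both.

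Markers of other cells were measured to describe what else the isolates held. T cell markers were lower in 7 of 11 cases (median -0.08, mean 0.01) and B cell markers in 9 of 15 (median -0.09, mean 0.03). The B cell list was called lower without phd3 null sample 3 (-0.99, adjusted p = 0.00720) and higher without wild-type sample 3 (0.72, adjusted p = 0.0264), the 2 arrays with most Cd79a. Monocyte and macrophage markers were lower in 8 of 13 cases (median -0.14), antigen presentation markers in 6 of 11 (median -0.05, mean 0.05), and eosinophil, basophil and mast cell markers in 2 of 3 (median -0.25). Platelet markers were lower in 3 of 7 cases (median 0.34, mean 0.05). When 1 array was left out, medians ran from -0.35 to 0.42 for T cell and -0.34 to 0.15 for monocyte and macrophage markers. They ran from -0.38 to 0.45 for antigen presentation, -0.68 to 0.15 for eosinophil, basophil and mast cell, and -0.22 to 0.50 for platelet markers. None of these removals gave a call for these lists. Erythroid markers were lower in 7 of 9 cases (median -0.35, adjusted p = 0.232), with Alas2 at -0.70 (SE 0.77), and were called lower without wild-type sample 1 (-0.62, adjusted p = 0.0373), but had a median of -0.05 without phd3 null sample 1 (adjusted p = 0.977) and -0.15 without wild-type sample 3. With all arrays and an estimated correlation, adjusted p was 0.994 for the B cell and the erythroid list. With every array kept, none of these 7 lists was called by camera in either fit, and 0 of their members passed over all genes or adjusted over the list alone.

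Genes near Egln3 can differ between strains when embryonic stem cell DNA stays around a targeted gene. Of 21 tested neighbours 7 were higher and 14 lower (median -0.11, camera adjusted p = 0.867), and 0 passed over all genes or adjusted over the list alone. The mixed test of fry, which asks whether genes of a list change in either direction, passed for this list with the block (adjusted p = 0.0160) and for 0 lists without it. Among the 40 tested genes nearest to Egln3 on chromosome 12 by start position, 1 had an unadjusted p under 0.05 in the paired fit, or 2.5%. Of all genes tested, 5.62% did.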

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

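Combinations of the replicate block with other settings, and the removal of whole pairs, were chosen after seeing the data. Without the block, limma called 0 genes in each setting with all 6 arrays and 0 or 1 when an array was left out, the 1 being Egln3 without wild-type sample 3. The Egln3 log2 fold change stayed between -4.68 and -3.37 over these removals. Without both arrays of pair 3 it was -4.81, again the 1 gene called. Over all settings Egln3 was lower (-4.81 to -3.14) and passed in 2 of 19 settings without the block.

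The replicate block called 2 genes, with Egln3 at -3.85 (adjusted p = 0.00140). Combined with the block, Egln3 was -4.18 with a pseudocount of 1 (2 genes called), -3.20 with 64 (4 genes), -3.85 with quantile normalization (1 gene, Egln3, with Ptgr1 lost), -3.88 with median centring (2 genes), -3.85 without a filter (6 genes), with the stricter filter (2 genes) and with every probe set (2 genes), and -3.89 with array quality weights (3 genes). An adjusted p under 0.10 gave 6. The mean of probe sets and eBayes without the trend gave 0 genes, with adjusted p for Egln3 of 0.495 and 0.896, so it passed in 12 of 14 block settings (adjusted p from 2.12e-50 to 0.896). The block without pair 1, 2 or 3 gave 9, 53 and 46 genes, with Egln3 at -3.60, -3.14 and -4.81. These 3 fits have 1 residual degree of freedom, and their spread comes almost wholly from the prior, with 127 prior degrees of freedom or an infinite number, so their counts and smallest p-values carry little weight. The block changed the calls of Egln3, Ptgr1 and the receptor and adhesion list and no other call over all genes or by camera among the reported genes and lists.

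Camera called 2 lists. There was 1 list with a pseudocount of 1 and with quantile normalization, 4 with array quality weights, and 1 to 6 when an array was left out. With an estimated correlation or fry there were 0. Without pair 1 or pair 2 there was 1, without pair 3 there were 3, and 0 without pair 3 with an estimated correlation. The block gave 3 lists, 5 with a pseudocount of 64, 6 with every probe set, 4 with the mean of probe sets, 1 without pair 1, 4 without pair 2 or pair 3, and 0 with an estimated correlation or fry. NK cell markers passed in 14 of 22 other settings without the block and 14 of 16 with it, and immediate early and heat shock genes in 11 and 13. Ribosomal protein genes ranged from -0.37 to 0.30 and B cell markers from -0.99 to 0.72 when an array was left out, the lowest value of each coming without phd3 null sample 3. The highest value of each came without wild-type sample 3, and without both arrays of pair 3 the medians were -0.09 and -0.18. Removing 1 array of pair 3 without the block leaves the replicate that stood apart in 1 genotype only. Such a removal therefore mixes replicate with genotype, and it also leaves fewer samples. The cause of these changes was not tested further. Low signal limits the dim genes, since no detection calls were used.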

Other observations

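The tests of gene patterns below, and the choice of the NRF2-regulated and redox genes, were made after the results were seen. A mixed set of redox genes, many of them known targets of the transcription factor NRF2, may be lower in phd3 null neutrophils. This is a hypothesis, since the set was chosen for a pattern seen in these data and of its 24 tested genes 1, Ptgr1, passed with the block. Gclm, Gclc, Txnrd1, Slc7a11 and Ptgr1 were noticed first, each lower in 3 of 3 pairs, with a median log2 fold change of -1.08. Of 25 further NRF2-regulated and redox genes, most of them outside glutathione and thioredoxin metabolism, 19 were tested and 18 were lower, 14 of them in every pair, with a median of -0.47. The median changed when 1 array was left out, to 0.06 without phd3 null sample 3, -0.17 without wild-type sample 1 and -0.97 without wild-type sample 3. Among them were Srxn1, which restores peroxiredoxins (-0.83), Hmox1 (-0.99), the autophagy receptor gene Sqstm1 (-0.52), catalase, Cat (-0.44), and thioredoxin, Txn1 (-0.48), while Ugdh was at 0.07. Over all genes 0 of these 19 passed with the block, and 1 of them, Hmox1, also stands in the HIF target list, fixed beforehand. List tests on genes chosen to extend a pattern already seen carry no weight, so their p-values are not given. The random-list percentiles of these genes below carry no weight for the same reason.

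Sources of the lower NRF2-regulated and redox genes were weighed on the 19 genes not noticed first. Whether the lower values rest on the replicate 3 arrays cannot be decided with these genes. Their medians in pairs 1 and 2 were -0.51 and -0.37, with percentiles of 0.01 and 0.10 among 10000 random lists matched on level. The genes were chosen after the results were seen, to extend a fall already noticed in these pairs, so low percentiles were likely from the start. Random lists do not keep the correlation between genes, so these percentiles may be too small. Negative magnetic selection is meant to remove monocytes and red cells, but fewer of either in the phd3 null isolates stay open. The monocyte markers' median lay 0.337 above that of these genes (95% bootstrap interval over genes 0.277 to 0.589), but without phd3 null sample 3 the gap was 0.0967 (-0.199 to 0.561). Fewer red cells or reticulocytes could also contribute, since several of these genes are active in red cell precursors. Erythroid markers had a median of -0.35 (pairs -0.58, -0.34 and -0.39), which lay 0.119 above that of these genes (-0.0598 to 0.543). This gap ran from -0.704 without phd3 null sample 3 to 0.816 without wild-type sample 3, so red cells stay open. Sex of the wild-type mice stays open, since 1 pair had similar Xist and Eif2s3y in both arrays, with a median of -0.51, and 1 pair decides nothing. Differences in culture or isolation between mice of the same pair stay open too. No effect of PHD3 inside neutrophils was tested apart from the genotype comparison.

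The lower NK cell markers could come from fewer NK cells in the phd3 null isolates, and no value tells this from lower expression per cell. The 13 markers varied together over the 6 arrays, with a median pairwise correlation of 0.783, at percentile 100 of random lists matched on level, but 3 other fixed lists were as coherent (ribosomal proteins 0.945, glycolysis 0.919, NADPH oxidase 0.818), and coherence over arrays does not bear on the genotype difference. Of the 13, 0 stand in another fixed list. Fewer lymphocytes of all kinds stay open. The median of T and B cell markers lay 0.519 above that of the NK cell markers (95% bootstrap interval 0.282 to 0.994), but the gap was 0.399 without phd3 null sample 3 (-0.439 to 0.959) and 0.296 without wild-type sample 2 (-0.170 to 0.689). Gzma, the brightest of the named markers, ranged from 228.4 to 1599.5 in phd3 null and from 789.7 to 3717.1 in wild type, and was lower in 3 of 3 pairs. Negative magnetic selection is meant to remove such cells, and whether PHD3 changes NK cell numbers was not tested.

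Xist and Eif2s3y differed between arrays in a way that may reflect the sex of the mice. By the brightest probe set of each gene, 5 of 6 arrays lay on opposite sides of the largest gap of each. The exception was phd3 null sample 3, low in both, which leaves sex undecided as the source for that array. The bounds of this test and of that of genotype below were set after the values were seen. The other Eif2s3y probe set was dim and did not follow the first, at 85 in phd3 null sample 3 and 1.7 in wild-type sample 1. A second Xist probe set was at 3.7 in phd3 null sample 3, against 695.3 and 476.7 in wild-type samples 2 and 3. The third Xist probe set was dim, at 37.1 in phd3 null sample 3 and 59.9 and 32.5 in those wild-type samples. Genotype alone was not excluded by the bound of 1 log2 unit for both genes. The range over the wild-type arrays exceeded that over the phd3 null arrays by 1.48 for Eif2s3y and by 0.65 for Xist. That bound compares the ranges, whereas genotype alone leaves no differences within a genotype beyond noise. Eif2s3y ranged over 3.39 log2 units in wild type and 1.91 in phd3 null, and Xist over 1.96 and 1.30. These ranges argue against genotype as the only source, though a part for it stays open. Wild-type sample 1 was about as high in Eif2s3y as phd3 null samples 1 and 2, but that is 1 array. Sex also stays open as a difference between wild-type samples 2 and 3 and their pairs, and the labels do not give it.

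Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. Without the block the real split called 0 genes, so 10 of 10 splits gave as many, the highest other giving 1. For lists the real split called 2 and the highest other 13, with 7 of 10 giving as many. That highest split sets phd3 null samples 1 and 2 with wild-type sample 1 against the rest. It had 1640 genes at an unadjusted p under 0.05, which points to a structure of the samples apart from genotype. Both replicate 3 arrays stand on 1 side of it. Other splits with both on 1 side had 882, 946 and 1188 such genes, and the rest 175 to 232. The highest split also parts high from low Eif2s3y (558.4 to 585.4 against 38.7 to 144.3), so its source is not settled. Among the 4 splits that part all pairs, the real one called 2 genes with the block (1 of 4, highest other 0) and 3 lists (2 of 4, highest other 4). The others differ in which genotype of a pair stands on which side. Of the 2 genes called in the real split, Egln3 is the targeted gene and differs there by design. Only Ptgr1 therefore bears on whether other splits call as many genes.

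Of 4441 tested probe sets without a single gene name, 0 passed without the block and 112 had an unadjusted p under 0.05. With the block 1 passed, at a log2 fold change of -1.47 (SE 0.20, adjusted p = 0.0212), lower in 3 of 3 pairs.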
